A study of Mus musculus with 6 samples.

How the data were processed

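Total RNA of mouse placentas was sequenced in 6 libraries, 3 from fetuses of zona-intact embryos and 3 from fetuses of zona-free embryos. Per the labels' protocols, RNA was extracted with ISOGEN II from 2 independent experiments and libraries were made for an MGI DNBSEQ sequencer. The submitters' processing notes name fastp, Bowtie2 2.0.0.5, TopHat2 2.0.0, StringTie 2.2.0 and the mouse genome build mm10, with no order or role. The annotation release, the strand setting and the step that made the values are not given in the sources used here.

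The authors deposited 1 table per library with TPM (transcripts per 1000000, that is abundance corrected for gene length and scaled to that sum) for 55487 Ensembl gene identifiers, and the same genes stood in every table. Gene names, positions and exon lengths were taken from GENCODE mouse release M21, which uses the same assembly (GRCm38, mm10), and 55227 identifiers matched while 260 did not. Coordinates are in GRCm38 and counted from 1. TPM is a share, so a large fall in a few abundant genes raises the others slightly, and the alternatives with other scalings address this.

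The depth behind TPM was recovered from the values. In each library TPM times the summed exon length of a gene fell on whole multiples of 1 step, and the step was taken as 1 read. With a tolerance of 0.02 reads, 98.5% to 98.6% of the values above 0 were whole. These recovered reads were 5729638, 21062730 and 5263236 for zona-intact replicates 1, 2 and 3, and 17436481, 21787379 and 20022198 for zona-free replicates 1, 2 and 3. A low value therefore has a coarser grid in zona-intact replicates 1 and 3 than in the other libraries. The recovered reads were used as a check and an alternative, not as the main measurement.

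The main test was limma 3.58.1 in R 4.3.3 with a mean-dependent prior variance on log2(TPM + 1), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes with a mean of at least 1 TPM over the 6 libraries were tested, 21060 in all. Fold changes from this fit are on the log2(TPM + 1) scale, which understates the change of low genes, and fold values without that word are ratios of mean TPM. A looser description counted genes with an unadjusted p under 0.05 and at least a 2-fold change. Errors of TPM are SDs over 3 libraries and errors of log2 fold changes are standard errors. Adjusted p-values called by reads come from limma-voom on the recovered reads of genes with a mean of at least 10 reads.

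Before the data were examined, 31 gene lists were fixed: markers of placental, maternal and blood cells, and pathways. They hold 851 distinct genes. The symbols Hbb-b1, Hbb-b2, Ahsp, Phf17, Figf, Pvrl2 and Pvrl3 did not match the annotation. Lists with at least 5 tested members were tested with camera, which compares a list with the other genes, with its preset correlation of 0.01. Camera with an estimated correlation, camera on ranks, camera on the recovered reads and fry were run beside it. A member was counted as passing over all genes tested, and again adjusted over the list alone. Some genes stand in more than 1 list, such as Slc2a1, Gjb2 and Fgfr1.

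The genes named were set by a rule fixed before the data were examined. It took the 10 largest positive and 10 largest negative log2 fold changes among genes past the threshold whose groups did not overlap, leaving predicted loci unnamed. It also took the 2 members of each list with the smallest p, and Tpbpa, Prl3b1, Syna, Synb, Gcm1, Igf2, H19, Cdkn1c, Phlda2, Peg10, Slc2a1, Slc38a4, Vegfa, Flt1, Kdr and Pgf whatever their values. Of the 10 largest rises 8 were short RNA loci, so the other protein-coding genes past the threshold and further list members were named after their values had been seen. The distance between libraries was Euclidean on log2(TPM + 1), with an exact permutation test over the 10 splits of 6 libraries.

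The tests were tried on simulated data with the real depths and means, 200 changed genes and a biological coefficient of variation of 10.1%. For this comparison the TPM test recovered 80% of 2-fold and 98% of 4-fold changes among 20956 simulated genes tested, and called 19 unchanged genes, 17 of them short loci. The read-based test recovered 98% and 100% among 19027 genes and called 14 unchanged genes. A list raised 1.5-fold was recovered with 0 other lists called. With no change simulated, neither limma test called a gene. The simulated genes varied independently, with the same coefficient of variation for all genes and libraries. The lack of other list calls was therefore largely set by the simulation. It does not show how camera behaves where the genes of a list vary together, or how either limma test behaves with unequal noise between libraries.

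The alternatives were other pseudocounts (0.1 and 5), no filter or a minimum of 5 TPM, median-of-ratios, TMM-type and quantile scaling, TPM without globin, mitochondrial and the top 20 genes, no variance trend, robust estimation, array weights, the replicate number as a block, no X- or Y-linked genes, the mean log2 level of 4 Y-linked genes as a covariate, recognised symbols only, and each library left out in turn. Added after the data had been examined were the read-based test, a minimum of 10 reads, protein-coding genes only, genes with at least 200 exonic bases, reads thinned to the depth of the shallowest library, and both shallow libraries left out, which sets 1 zona-intact library against 3 and assumes that it varies like them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.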

Results

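RNA sequencing was used to compare placentas of mouse fetuses that developed from embryos with or without a zona pellucida, the glycoprotein coat of the egg and early embryo. Embryos of the outbred ICR strain were made by in vitro fertilisation with females aged 8 weeks. The zona was removed after the 2-cell stage in the zona-free group and left in place in the zona-intact group, and blastocysts were transferred to recipients at embryonic day E3.5. Each group had 3 placenta libraries. The series design dates the placentas to embryonic day E17.5, whereas the age given with each sample is birth, so the stage is taken here from the design. The labels do not say whether the replicates came from separate dams or litters, so p-values measure the spread between these samples.

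The deposited values were transcript abundances as TPM (transcripts per 1000000 transcripts) for 55487 genes in each of the 6 libraries. Multiplied by exon length they were whole multiples of 1 step per library, within 0.02 of a read for 98.5% to 98.6% of the values above 0, and this gave the reads behind each value. Zona-intact replicates 1 and 3 rested on 5729638 and 5263236 reads, and zona-intact replicate 2 on 21062730. The zona-free replicates rested on 17436481, 21787379 and 20022198 reads. The deepest library held 4.14 times the reads of the shallowest. Genes with a TPM above 0 numbered 25799 ± 3300 (SD, n = 3) in zona-intact and 30378 ± 462 (SD, n = 3) in zona-free placentas. In a gene with 1000 exonic bases, 1 read was worth 0.52 TPM in zona-intact replicate 1 and 0.133 TPM in zona-intact replicate 2.

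**Figure D1:**
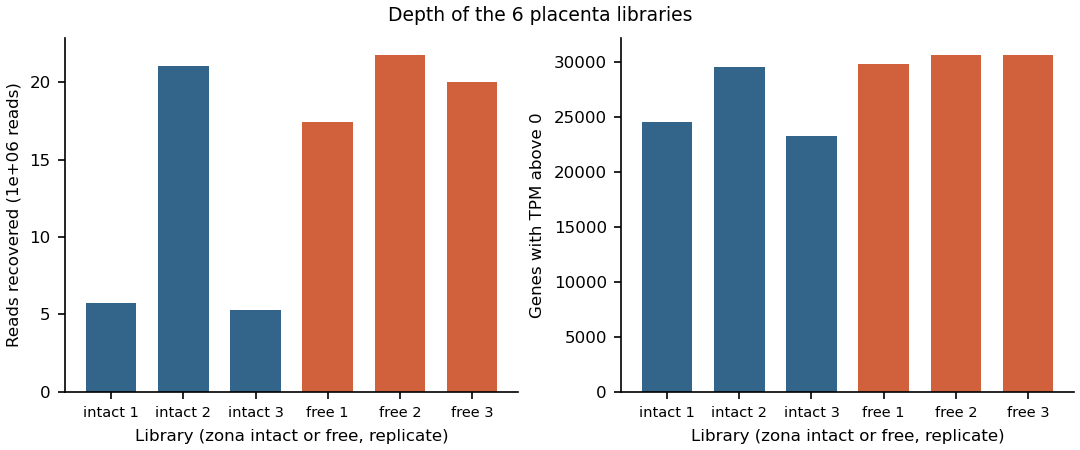
Bars show, for each of the 6 placenta libraries, the reads recovered from the deposited TPM (left, axis in units of 1e+06 reads) and the number of genes with a TPM above 0 (right). Zona-intact replicates 1 and 3, with 5729638 and 5263236 reads, stand below the other libraries, which hold 17436481 to 21787379.

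Transcripts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in zona-intact replicate 1 and zona-free replicates 1 and 3. In these 3 libraries Xist, the RNA that silences an X chromosome in females, stood at 178, 172 and 162 TPM. In the other 3 libraries Xist stood between 7.72 and 16.8 TPM, and Ddx3y between 36.5 and 41.4 TPM. By these transcripts the zona-intact group held 1 female and 2 male placentas, and the zona-free group 2 female and 1 male.

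The question of the comparison was whether removing the zona from the embryo goes with a different placental transcriptome late in gestation. Over all genes the zona-free placentas had lower levels of the adult globin genes, Alas2 and Gzme, and higher levels of the protease gene Ctsk, the membrane protein genes Gpnmb and Serinc5, and the receptor genes Erbb3, Cxcr4 and Fgfr1. On the TPM scale, and only when adjusted within gene lists, several nutrient transport and syncytiotrophoblast transcripts were lower and a group of interferon-induced genes higher. Of 21060 genes with a mean of at least 1 TPM, 68 passed an adjusted p of 0.05 by limma on log2(TPM + 1). Of these 52 were higher and 16 lower in zona-free placentas. Among protein-coding genes 26 were higher and 15 lower. A test on the recovered reads (limma-voom) called 415 of 19062 genes, 196 higher and 219 lower, and it also called 40 of the 41 protein-coding genes. With 1 library left out the counts ranged from 0 to 114 by TPM and from 179 to 269 by reads, with each value given at the end. The read-based test and the added ones named here were chosen after the data had been examined.

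Globin transcripts showed a large difference in abundance. All globin genes together made up 5.48% ± 1.13 (SD, n = 3) of TPM in zona-intact placentas and 1.34% ± 0.126 (SD, n = 3) in zona-free placentas, with 4.18% to 6.21% in the first group and 1.21% to 1.46% in the second. The adult alpha-globin gene Hba-a1 (ENSMUSG00000069919, chromosome 11, 32283511 to 32284465, GRCm38) fell from 24532 ± 5651 to 5893 ± 707 TPM. Its log2 fold change was -2.04 ± 0.26 (SE; adjusted p = 0.0435). The adult beta-globin gene Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096) fell from 13004 ± 2412 to 3047 ± 291 TPM, a level 4.27-fold lower (adjusted p = 0.0248). Hba-a2 and Hbb-bt fell by 1.94 and 1.91 on the log2 scale. Each of these genes has a near-identical neighbour with which reads can be shared, so the division within each pair is uncertain.

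Alas2, the erythroid enzyme that starts haem synthesis, fell from 149 ± 26.9 to 45.0 ± 2.95 TPM (adjusted p = 0.0248). Of the 13 tested members of the erythroid and globin list, all had a lower mean in zona-free placentas, 5 fell over all genes and 6 fell when adjusted over the list alone. The list as a whole was lower by camera with a preset correlation (adjusted p = 5.92e-14), with a median log2 fold change of -1.52 (adjusted p = 0.317 with an estimated correlation). The red-cell membrane genes Slc4a1, Gypa, Spta1 and Epb42 had read-based log2 fold changes of -0.48 ± 0.30, -0.71 ± 0.38, -0.59 ± 0.31 and -1.74 ± 0.52 (SE), none past the threshold.

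**Figure D2:**
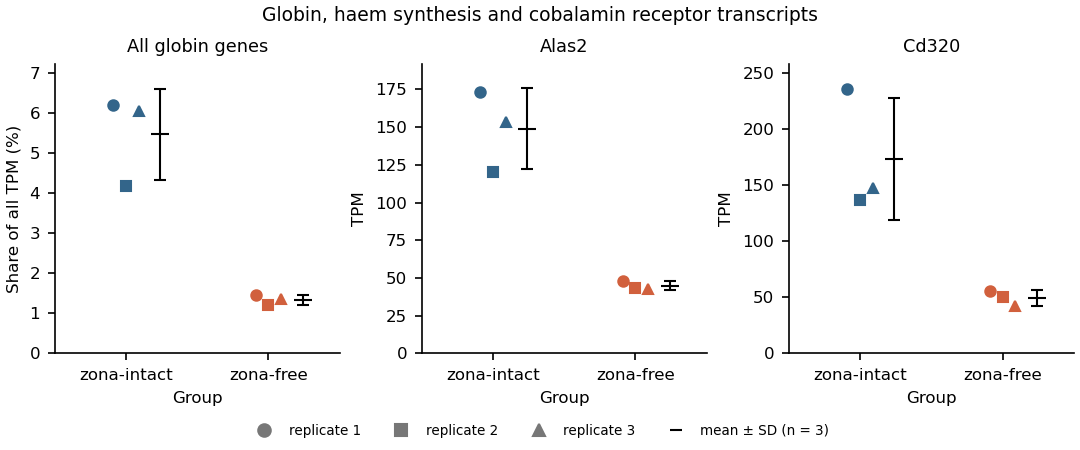
Points show each placenta library for the share of all TPM taken by globin genes in percent (left), for Alas2 in TPM (middle) and for Cd320 in TPM (right), with marker shapes for replicates and the black bars giving the mean and SD of 3 libraries. The zona-free libraries lie between 1.21% and 1.46% for globin and the zona-intact libraries between 4.18% and 6.21%.

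The other genes called lower had separate ranges in the groups, which the naming rule required of the 10 largest falls. Gzme (ENSMUSG00000022156, chromosome 14, 56117626 to 56120625), a granzyme gene of cytotoxic granules, fell from 19.2 ± 3.74 to 1.64 ± 0.755 TPM, a level 11.7-fold lower (adjusted p = 0.0248). Its neighbours Gzmd and Gzmf also fell when adjusted over the natural killer and T cell list alone, and reads can be shared among these genes. That list was called lower (7 tested members, adjusted p = 2e-04 by camera and 0.287 with an estimated correlation), although Ccl5 and Il2rb had log2 fold changes of 1.04 and 0.08. Cd320, the cellular receptor for vitamin B12 bound to its carrier, fell 3.5-fold, from 174 ± 54.6 to 49.6 ± 6.81 TPM. Ear6, an eosinophil-associated ribonuclease, fell 5.62-fold, the solute carrier gene Slc35f2 2.94-fold and the pantetheinase gene Vnn1 2.18-fold. Plac1, an X-linked gene of the placenta, fell from 74.0 ± 1.82 to 38.2 ± 5.61 TPM. The remaining protein-coding genes called lower were Plbd1, Tubb3, Naga and Decr1, which fell by 0.87 to 1.02 on the log2 scale.

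Transcripts of the labyrinth syncytiotrophoblast, the fused cell layers through which the fetus is supplied, were lower in zona-free placentas. Of 26 tested members 22 had a lower mean, none passed over all genes, and 11 fell when adjusted over the list alone. Gcm1, a transcription factor needed for syncytiotrophoblast to form, fell from 33.3 ± 4.17 to 11.3 ± 4.23 TPM. Its adjusted p was 0.0968 over all genes and 0.0137 by reads. Within the list the lactate and ketone transporters Slc16a3 and Slc16a1, the glucagon receptor gene Gcgr, the fusion protein gene Synb, the gap junction gene Gjb2 and the transcription factor gene Dlx3 also fell, by 0.65 to 1.15 on the log2 scale. Syna had a log2 fold change of -0.47 ± 0.27 (SE) that did not pass. By camera the list was lower with an adjusted p of 1.48e-10 (adjusted p = 0.428 with an estimated correlation). Over the list's genes the read-based test called 9 as lower, of which Gcm1, Slc16a3, Synb and Slc2a1 were followed with libraries left out. By reads Gcm1 was called with any 1 library left out (adjusted p = 0.0191 to 0.0408). Slc16a3 was not called without zona-free replicate 3 (adjusted p = 0.0609), Synb without any 1 zona-intact library or zona-free replicate 1 (adjusted p = 0.0615 to 0.0829), and Slc2a1 without zona-intact replicate 1 or 3 or zona-free replicate 2 or 3 (adjusted p = 0.121 to 0.139). In these fits the read-based log2 fold changes were -1.18 for Slc16a3, -0.82 to -0.92 for Synb and -0.64 to -0.70 for Slc2a1, against -1.23, -0.85 and -0.76 with all libraries.

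Nutrient transporters overlapped with this group and moved the same way. Of 39 tested members 14 fell and 1 rose when adjusted over the list alone, and over all genes only the rise passed. Slc7a5, a carrier of large neutral amino acids, fell from 366 ± 88.2 to 163 ± 26.5 TPM. The folate receptor gene Folr1 fell from 142 ± 39.0 to 52.0 ± 15.9 TPM, Mfsd2a, a lysophospholipid transporter, from 63.9 ± 15.4 to 31.2 ± 1.15 TPM, and the glucose transporter gene Slc2a1 from 1408 ± 270 to 883 ± 215 TPM. The member that rose was the cholesterol exporter Abcg1, from 58.5 ± 0.605 to 113 ± 5.26 TPM (adjusted p = 0.0248 over all genes). The list was lower by camera (adjusted p = 1.25e-11, and adjusted p = 0.428 with an estimated correlation).

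Among the genes called higher, Ctsk (ENSMUSG00000028111, chromosome 3, 95499256 to 95509362), which encodes the lysosomal protease cathepsin K, rose from 7.45 ± 1.71 to 88.8 ± 35.5 TPM. That was an 11.9-fold higher level (adjusted p = 0.0248), and by reads the call was lost without zona-intact replicate 2 (adjusted p = 0.0741). Its read-based log2 fold change was 3.58 ± 0.79 (SE) there against 3.28 ± 0.50 with all libraries, so the wider error and not a smaller change ended the call. The same fit did not call Tmem114, Hpgd and Cxcr4 (adjusted p = 0.0669, 0.0651 and 0.0777), with log2 fold changes of 3.34, 1.43 and 1.25 against 3.22, 1.39 and 1.32. Tmem114 rose from 1.36 ± 0.573 to 14.8 ± 3.01 TPM. Gpnmb, a lysosomal membrane glycoprotein gene, rose 3.58-fold, the serotonin receptor gene Htr1d 3.28-fold, the transcription factor gene Sox11 3.05-fold and Hpgd, which inactivates prostaglandins, 2.78-fold. Serinc5 rose from 126 ± 12.2 to 314 ± 23.2 TPM. Erbb3, a receptor of the epidermal growth factor receptor family, rose from 41.8 ± 6.73 to 97.1 ± 3.93 TPM. The chemokine receptor gene Cxcr4 rose 2.59-fold, the gap junction gene Gja4 2.53-fold, and Fgfr1 from 125 ± 11.1 to 231 ± 24.4 TPM. Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, rose from 59.2 ± 8.996 to 113 ± 0.834 TPM. The 3 zona-free values of each gene in this paragraph lay above all 3 zona-intact values, which choosing genes past the threshold largely ensures.

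**Figure D3:**
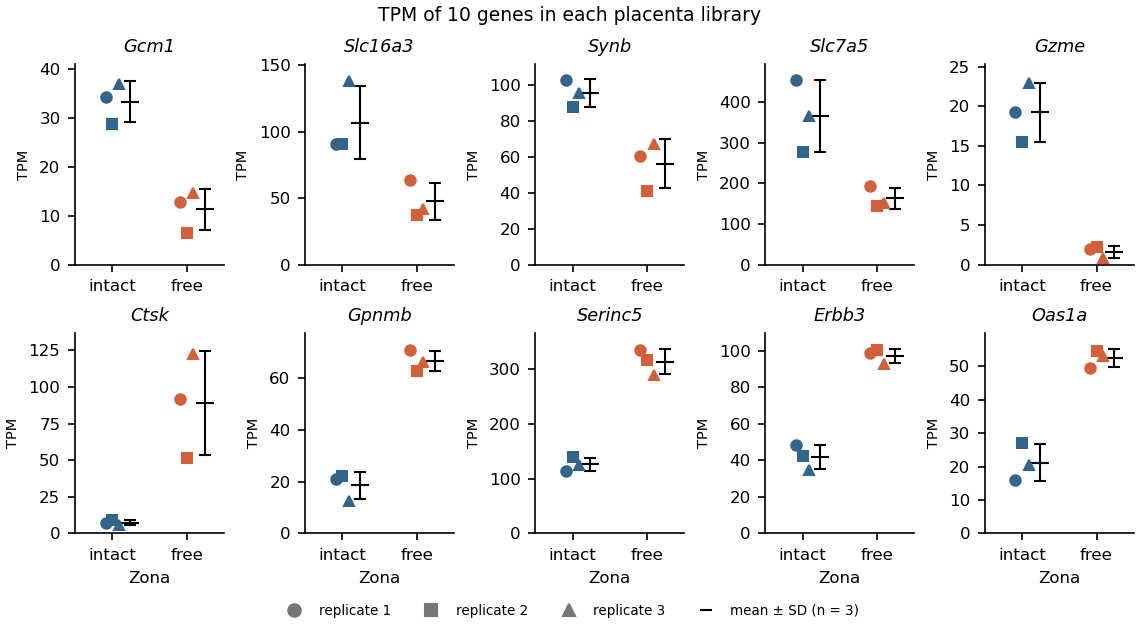
Each panel shows the TPM of 1 gene in the 6 placenta libraries, blue for zona-intact and orange for zona-free, with marker shapes for replicates and black bars for the mean and SD of 3 libraries. Gcm1, Slc16a3, Synb, Slc7a5 and Gzme lie lower in all zona-free libraries, and Ctsk, Gpnmb, Serinc5, Erbb3 and Oas1a lie higher in them.

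Short RNA loci made up much of the remaining higher calls. Of the 52 higher calls 23 had fewer than 200 exonic bases, 13 of them microRNA loci, and 20 of the 23 were listed at 0 in every zona-intact library. They rested on a median of 4 reads per zona-free library, and 22 of them lay inside or across another annotated gene, where reads of that gene can be counted. Mir26b (chromosome 1, 74394310 to 74394394, within Ctdsp1) had 11, 5 and 6 reads in the zona-free libraries and Mir5616 (chromosome 4, within Ctnnbip1) had 5, 7 and 3. Mir7681, Mir7081, Mir7030, Mir26a-1, Mir1195 and the ribosomal RNA locus n-R5s40 were likewise listed at 0 in the zona-intact group, with 2 to 6 reads in each zona-free library. None of these 8 loci had enough reads to enter the read-based test.

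Interferon-induced genes were the only list called higher by camera with a preset correlation (adjusted p = 2.55e-09, and adjusted p = 0.287 with an estimated correlation). Camera on ranks called 2 lists higher, this one and spongiotrophoblast. Of 32 tested members 29 had a higher mean in zona-free placentas, none passed over all genes, and 17 rose when adjusted over the list alone. Oas1a, an antiviral enzyme, rose from 21.1 ± 5.50 to 52.4 ± 2.65 TPM (adjusted p = 0.0568 over all genes and 0.0158 by reads). Usp18, Oasl2 and Gbp2 rose within the list by log2 fold changes of 0.91, 0.83 and 1.08, and Irf7, Ifit1 and Isg15 by 0.64, 0.70 and 0.48. The read-based call of Usp18 was lost without any 1 library except zona-free replicate 1 (adjusted p = 0.0664 to 0.0783), with log2 fold changes of 0.76 to 0.98 against 0.81. The fry test, which asks whether the genes of a list move one way, gave an adjusted p of 0.0257.

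In total 12 of 31 lists fixed before the data were examined were called by camera with its preset correlation, 11 lower and 1 higher. No list was called with an estimated correlation, where the smallest adjusted p was 0.287 and 4 lists had an unadjusted p under 0.05. With quantile normalization 9 lists were called, 6 lower and 3 higher. Other splits of the 6 libraries into 3 against 3 also called lists, up to 17, and 5 of the 10 splits, the real one included, called at least 12. By fry for change in 1 direction, 3 lists were called, namely erythroid and globin, interferon response, and natural killer and T cell. The read-based camera test called 13 lists, 11 lower and 2 higher. Nuclear genes of oxidative phosphorylation were lower by a median of only 0.20 on the log2 scale, with 63 of 73 members negative (camera adjusted p = 1.8e-11, and adjusted p = 0.428 with an estimated correlation). On the TPM scale no member passed the threshold, while by reads Atp5d and Atp5b were called lower. The yolk sac visceral endoderm list was lower (adjusted p = 0.000133, and adjusted p = 0.428 with an estimated correlation) with 11 of 16 members negative. The members that fell when adjusted over the list alone were the retinol carrier gene Rbp4, from 59.1 ± 16.8 to 8.71 ± 4.79 TPM, and the apolipoprotein gene Apob, from 14.4 ± 7.38 to 3.58 ± 1.32 TPM.

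The glycogen trophoblast list was lower with no member past the threshold (adjusted p = 0.00129, and adjusted p = 0.287 with an estimated correlation). Hypoxia response genes had a median of -0.14 (adjusted p = 0.00584, and adjusted p = 0.818 with an estimated correlation). Cytosolic ribosomal proteins, cell junction genes, and fetal endothelium and pericytes had adjusted p-values of 0.0219, 0.0368 and 0.0368, each with an adjusted p of 0.901 with an estimated correlation. Their medians were -0.03, -0.0012 and -0.06. The mean of the ribosomal list was 0.02, opposite in sign to its median and its test, which compares a list with the other genes. The median log2 fold change was 0.11 over all genes tested and 0.06 over protein-coding genes. A list with a median near 0 can therefore be called lower. In the cell junction list F11r and Dsg2 rose and Cldn3, Gjb2 and Itga5 fell when adjusted over the list alone.

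**Figure D4:**
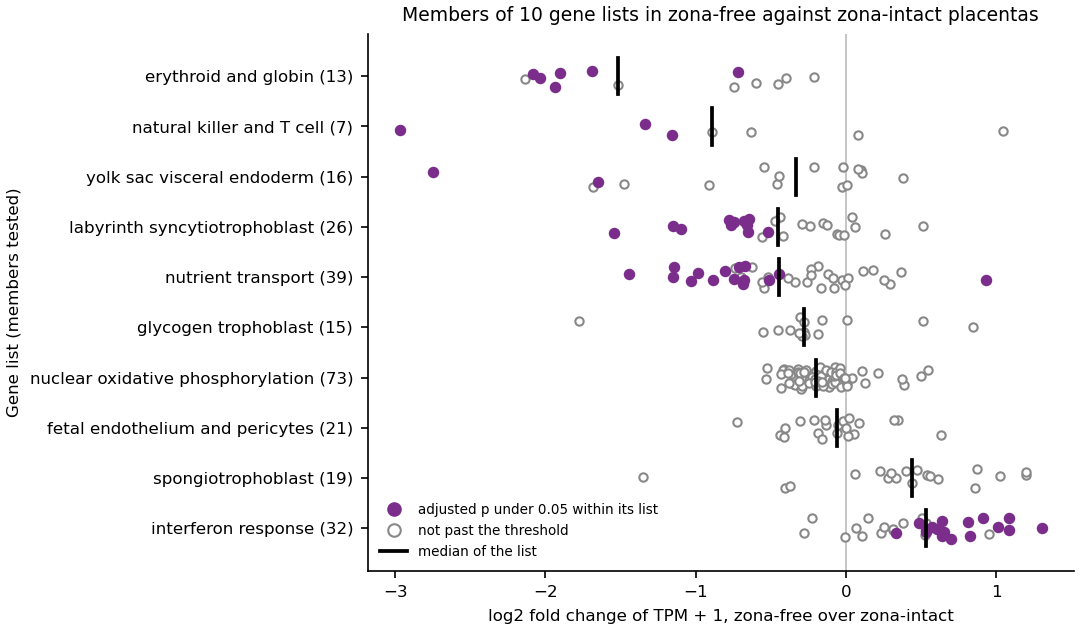
Each point is 1 tested member of 1 of 10 gene lists, placed by its log2 fold change of TPM + 1 in zona-free over zona-intact placentas. Purple points passed an adjusted p of 0.05 within their list, and black bars mark medians, which range from -1.52 for erythroid and globin genes to 0.53 for interferon-induced genes.

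Spongiotrophoblast genes, which mark the junctional zone, had a median log2 fold change of 0.44 with 16 of 19 members positive and an adjusted p of 0.0759, short of the threshold. By reads the camera adjusted p was 0.0103, whereas on the TPM scale with an estimated correlation it was 0.901. Without zona-intact replicate 1 the list ranked below the other genes. Tpbpa stood at 7699 ± 2484 TPM in zona-intact and 13496 ± 1659 TPM in zona-free placentas (adjusted p = 0.27), and Ceacam13 and Prl3a1 had log2 fold changes of 1.20 each that did not pass on the TPM scale. The trophoblast giant cell list held members that moved both ways (median 0.17, adjusted p = 0.522 by camera, and adjusted p = 0.000351 for change in either direction by fry). Fry for change in either direction called 16 of the 31 lists, so such a call is not particular to giant cell genes. Its smallest adjusted p, 7.6e-08, was that of the endoplasmic reticulum stress list, which camera did not call. Ctsm and Prl2a1 rose, and Lepr, Ctsr and Cts6 fell, when adjusted over the list alone. Placental prolactin genes had a median of 0.35 (adjusted p = 0.656).

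Camera did not call the lists of 3 other kinds of cell a placenta sample can hold. Maternal decidua had a median log2 fold change of -0.02, uterine smooth muscle -0.04 and macrophage and neutrophil genes -0.07, with adjusted p-values of 0.219, 0.219 and 0.356. Imprinted genes had a median of 0.03 (adjusted p = 0.285), with Peg3 and Pde4d rising and Slc22a18 falling when adjusted over the list alone. Igf2, H19, Cdkn1c, Phlda2, Peg10 and Slc38a4 had log2 fold changes of 0.51, -0.28, 0.01, -0.01, -0.15 and 0.18, none past the threshold. Angiogenesis genes had a median of 0.00083 (adjusted p = 0.219), with Fgfr1 rising and Apln and Thbs2 falling within the list, while Vegfa, Flt1, Kdr and Pgf had log2 fold changes of -0.42, 0.28, -0.002 and 0.27.

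The other lists were not called by camera. Antioxidant genes had a median of -0.08 (adjusted p = 0.0833), lineage regulators of the early embryo -0.05 (0.171), mitochondrially encoded genes -0.009 (0.262) and immediate early and heat shock genes -0.01 (0.306). Extracellular matrix genes had a median of 0.20 (adjusted p = 0.285), cell proliferation genes 0.01 (0.356), DNA methylation genes 0.09 (0.522) and steroid and cholesterol synthesis genes 0.14 (0.768). Insulin-like growth factor signalling, endoplasmic reticulum stress, and apoptosis and p53 target genes had medians of 0.04, 0.08 and 0.08 (adjusted p = 0.768, 0.903 and 0.959). Mean and median had opposite signs in the antioxidant, angiogenesis, imprinted, immediate early, macrophage and DNA methylation lists. The cell proliferation, insulin-like growth factor and endoplasmic reticulum stress lists had positive medians below the 0.11 of all genes, and their test direction was lower. The direction was also lower for the trophoblast giant cell list, although its median of 0.17 lay above that of all genes. In the DNA methylation list Dnmt3l fell, when adjusted over the list alone, from 25.5 ± 2.63 to 14.7 ± 1.20 TPM.

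Across all genes the mean distance between libraries of different groups exceeded that within groups by 12.5 on the log2 scale (exact permutation test, upper tail, p = 0.1, the smallest that 10 splits allow). The mean distance was 82.2 within zona-free, 121 within zona-intact and 114 between groups. The distances also followed depth, since the deep zona-intact replicate 2 lay nearer to each zona-free library (86.9 to 95.5) than to zona-intact replicates 1 and 3 (112 and 111). Values of the groups did not overlap in 4438 genes, 21.1% of those tested, against 10% for a gene with its values in random order. That excess was not tested. Genes share the same libraries, and both shallow libraries were zona-intact. At the looser limit of an unadjusted p under 0.05 and a 2-fold difference, 684 genes were higher and 160 lower. This split was 532 to 191 with median-of-ratios scaling, 558 to 185 with TMM-type scaling, 393 to 307 with quantile normalization and 543 to 213 by reads. Of the 684 higher genes, 244 had fewer than 200 exonic bases. Among protein-coding genes 172 were higher and 97 lower at this limit.

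The calls depended on scaling. Higher and lower calls numbered 37 and 21 with median-of-ratios scaling, 42 and 30 with TMM-type scaling and 33 and 17 with quantile normalization, and these included 47, 49 and 40 of the 68 genes. The median log2 fold change of all tested genes was 0.11 as deposited and -0.02 after quantile normalization. The count of 68 genes did not hold when libraries were left out, with 2, 114 and 1 calls without zona-intact replicates 1, 2 and 3, and 1, 0 and 0 calls without zona-free replicates 1, 2 and 3. The read-based test called 197, 204 and 253 genes without zona-intact replicates 1, 2 and 3, and 269, 193 and 179 without zona-free replicates 1, 2 and 3. With the Y-linked level as a covariate limma called 0 genes on the TPM scale and 838 by reads. In the TPM fits with 0 calls, 913 genes with that covariate, 708 without zona-free replicate 2 and 777 without zona-free replicate 3 had an unadjusted p under 0.05 and at least a 2-fold difference.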

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

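The tests on recovered reads, with thinned reads, with a minimum of 10 reads, with protein-coding or longer genes only, and without both shallow libraries were chosen after the data had been examined. The count of 68 genes was within 1.5 times of its value with a pseudocount of 5, a minimum of 5 TPM, the 3 other scalings, TPM without the most abundant genes, no trend, robust estimation, no X- or Y-linked genes, at least 10 reads, at least 200 exonic bases, and 1 draw of thinned reads, with 50 to 91 calls. Over 10 draws of thinned reads it ranged from 27 to 92 with a median of 56.5. It was 34 with a pseudocount of 0.1, 0 with no TPM filter (limma; 1004 genes at an unadjusted p under 0.05 and 2-fold), 906 with array weights, 0 with the Y-linked covariate, 121 with recognised symbols, 415 by reads, 182 with protein-coding genes only and 1 without both shallow libraries. With recognised symbols and protein-coding genes fewer genes were tested, and all main calls among them were kept (50 of 50 and 41 of 41). The cause of the changed count was not tested for any of these alternatives. Array weights gave zona-intact replicate 2 a weight of 4.22 and zona-intact replicates 1 and 3 weights of 0.318 and 0.395. Leaving out 1 library gave 0 to 114 genes, and the read-based test still called 34 to 42 of the 44 testable main calls in those fits. Those 44 genes had been chosen with all 6 libraries, and the fits reuse the remaining ones. Most were therefore likely to pass again, and the number kept is no measure of how stable the calls are.

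The read-based count of 415 ranged from 179 to 269 with 1 library left out, and was 838 with the Y-linked covariate and 28 without both shallow libraries, which also kept 13 of the 44 main calls. Without both shallow libraries the zona-intact group is 1 library, assumed to vary like the zona-free group, so calls lost there do not show that a result is unstable. The looser count of 844 fell to 231 with a pseudocount of 5, 352 with a minimum of 5 TPM, 397 with recognised symbols, 455 with at least 10 reads and 287 with protein-coding genes, all of which test fewer low genes or shrink them, and ranged from 702 to 1222 with 1 library left out. The 12 lists became 0 with an estimated correlation (limma camera; 4 lists at an unadjusted p under 0.05, and 3 by fry for change in 1 direction) and 10 to 15 with 1 library left out. They became 9 with a minimum of 5 TPM, quantile normalization, recognised symbols or protein-coding genes only. With median-of-ratios or TMM-type scaling they became 14, and with array weights 16. The distance between groups kept its sign in all 4 alternatives tried.

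The replicate numbers were not found to pair the libraries, since the deviations of same-numbered libraries correlated at 0.028, 0.017 and -0.038 and not every library correlated best with its own number. With the replicate block the TPM test called 1 gene, 864 by the looser limit and 12 lists, and the read-based test 619 genes.

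All changes of direction were in genes and lists not past the threshold, whose values (log2 fold changes, for lists the mean of members, with direction judged against the other genes) mostly lay near 0, exceptions being Syna at -0.47, H19 at -0.28, the spongiotrophoblast list at 0.38 and the prolactin list at 0.21, and their cause was not tested. Cdkn1c turned to -0.0842 with median-of-ratios scaling, -0.0653 with TMM-type scaling, -0.0452 without abundant genes, -0.0727 with the Y-linked covariate and -0.062 by reads. Kdr turned to 0.00108 with a pseudocount of 5 and 0.0725 with thinned reads, and Phlda2 to 0.21 with thinned reads. Peg10 turned to 0.0478 with quantile normalization, 0.112 with array weights and 0.176 without both shallow libraries, Prl3b1 to 0.197 with quantile normalization, and Syna and H19 to 0.132 and 0.0247 without both shallow libraries. The apoptosis list turned at 0.0851 with no filter, -0.00188 with median-of-ratios scaling, 0.0154 with TMM-type scaling, 0.036 without abundant genes, 0.0301 with the Y-linked covariate, 0.0218 by reads and 0.0753 with thinned reads. The endoplasmic reticulum stress list turned at 0.0884 with a minimum of 5 TPM, recognised symbols or protein-coding genes, 0.0598 with quantile normalization and 0.0959 with the Y-linked covariate. The insulin-like growth factor list turned at 0.0596 with a minimum of 5 TPM, -0.0122 with quantile normalization, 0.0858 with array weights and 0.152 without both shallow libraries. The trophoblast giant cell list turned at 0.114 with quantile normalization, 0.209 without abundant genes and 0.229 with the Y-linked covariate, and the imprinted list at -0.0517 with quantile normalization and 0.102 without both shallow libraries. With array weights and without both shallow libraries, in that order, the spongiotrophoblast list turned at 0.0839 and 0.000339, the prolactin list at 0.131 and 0.0579, the mitochondrially encoded list at 0.148 and 0.166, and the steroid list at 0.021 and 0.0363.

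With 1 library left out the ranges were -0.281 to 0.129 for Phlda2, -0.149 to 0.242 for Kdr and -0.0802 to 0.125 for Cdkn1c. They were 0.112 to 0.57 for the spongiotrophoblast, -0.0851 to 0.122 for the imprinted, 0.059 to 0.319 for the prolactin, -0.0302 to 0.16 for the insulin-like growth factor, 0.0318 to 0.159 for the endoplasmic reticulum stress, 0.0118 to 0.172 for the apoptosis, 0.0335 to 0.242 for the trophoblast giant cell, -0.179 to 0.0595 for the mitochondrially encoded, 0.00577 to 0.146 for the steroid, -0.217 to 0.0991 for the decidua and -0.19 to 0.228 for the macrophage and neutrophil list. For single genes and lists, 3128 of the other values kept direction and side of the threshold, 635 lost the threshold and 138 gained it. The 3128 include genes and lists that passed in neither fit, and only main calls could lose the threshold. That count is therefore no measure of how stable the calls are. Setting genes missing from a table to 0 was not run because every table lists the same genes, and FPKM was not run because the tables hold TPM. Depth limits low genes most, since 1 read in a gene with 1000 exonic bases is worth 0.52 TPM in the shallow zona-intact replicate 1.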

Other observations

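The tests of blood content, labyrinth share and few reads per locus, and all read-based values, were chosen after the results they bear on had been seen. The read-based test called placental genes that the comparison described briefly or not at all, and those given here were chosen after their values had been seen. Of the cathepsin cluster on chromosome 13, Ctsj, Ctsq, Ctsr and Cts6, proteases made by trophoblast, were lower in zona-free placentas with read-based log2 fold changes of -0.75, -0.67, -0.68 and -1.15, while their neighbour Ctsm was higher by 1.17 (limma-voom adjusted p = 0.0204, 0.0277, 0.0105, 0.0172 and 0.00511). Reads can be shared within this family. Placental cathepsins together took 4.10%, 3.39% and 4.11% of TPM in the zona-intact libraries and 2.23%, 2.80% and 2.56% in the zona-free libraries. Lepr, the leptin receptor gene, was lower, with a log2 fold change of -0.82 (adjusted p = 0.0109), and Prl2a1 higher by 1.37 (adjusted p = 0.00395). Ceacam15 stood at 136 ± 71.3 TPM in zona-intact and 660 ± 147 TPM in zona-free placentas (SD, n = 3, read-based adjusted p = 0.0098).

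Nppb, which encodes a natriuretic peptide, stood at 100 ± 42.3 and 317 ± 56.1 TPM, Mdk, a heparin-binding growth factor, at 42.6 ± 12.6 and 133 ± 24.7 TPM, and the chemokine Cxcl14 at 14.0 ± 5.99 and 53.8 ± 14.6 TPM in zona-intact and zona-free placentas. Their read-based log2 fold changes were 1.58, 1.56 and 2.07 (adjusted p = 0.0109, 0.0098 and 0.00748). Pparg, a regulator of labyrinth trophoblast, and the carbonic anhydrase gene Car4 were lower, with log2 fold changes of -0.62 and -0.99 (adjusted p = 0.0109 and 0.00698). In each of these genes all 3 zona-free values lay on 1 side of all 3 zona-intact values, which choosing genes past the threshold makes likely.

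Lower globin transcripts can come from fewer reads, from less blood in the tissue or from a difference in the red cells themselves. With all libraries thinned to 5263236 reads the 4 adult globin genes kept a mean log2 fold change of -1.988 (median of 10 draws, which ranged from -1.994 to -1.985). Thinning leaves the expected share of genes with this many reads unchanged, so this outcome was close to fixed. It shows only that unequal read numbers as such do not make the fall. A sequencing run or experiment that differs along with depth cannot be addressed this way. Less blood remains open. A smaller share of blood would lower red-cell transcripts alike only if red cells alone made them and their own make-up stayed the same. Neither condition was tested. The 8 erythroid genes other than globins had a median read-based log2 fold change of -0.65, with all 8 negative. They lay between -1.75 for Alas2 and -0.48 for Slc4a1. The median lies between the fall of the globins and no change. Blood content and a change within the red cells therefore cannot be told apart here, and zona removal itself stays an untested explanation.

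The short loci called higher can be products of few reads. In reads simulated at the real depths, with no change at short loci beyond the seeded genes, the TPM test called 17 unchanged short loci. It called 0 when no gene was changed, so few reads per locus can give such calls where other genes change. The data gave 23, but the counts are not comparable in size. The simulation was a single draw with 200 changed genes, against 68 calls in the data, and more passing genes loosen the adjusted threshold. At 1 depth the test called a median of 24.5 short loci, which by the rule set before the data were examined goes against unequal depth. The count spread from 10 to 41 over 10 draws, with a median of 7 of the 23 original loci kept. Whether unequal depth made those 23 calls therefore cannot be told. A general length effect also stays open. The 273 short loci with at least 10 reads lay above longer genes by 0.28 in median log2 fold change, less than the calls would need. The 95% bootstrap interval of 0.231 to 0.348 resampled loci that share the same 6 libraries. It measures spread over loci and cannot show that the shift differs from none between placentas. No biological explanation was tested for these loci.

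Lower syncytiotrophoblast transcripts can reflect how much labyrinth each sample held, which cannot be told apart from a change within its layers. Less labyrinth would lower its endothelium alike, but relative to the zona-intact group the endothelium score stood 0.34 ± 0.07 (SE) above the syncytiotrophoblast score on the log2 scale. This does not exclude less labyrinth, since endothelial genes also mark vessels outside it. Their list was itself lower by camera (adjusted p = 0.0368), but not with an estimated correlation (adjusted p = 0.901). The junctional spongiotrophoblast score stood 0.38 ± 0.28 (SE) higher, the direction a smaller labyrinth share would give. That list did not pass (camera adjusted p = 0.0759), and its mean log2 fold change was 0.112 without zona-intact replicate 1. At 1 depth the mean log2 fold change of the list was -0.44 (-0.45 to -0.41 over 10 draws). Thinning hardly moves the expected share of a gene, so this shows only that unequal read numbers as such do not make the fall. A run or experiment that differs along with depth stays open. Fetal sex is argued against by -0.50 with the Y-linked level as a covariate. A change within the syncytiotrophoblast layers after zona removal, for which lower Gcm1 is a lead, stays untested, and counts of syncytiotrophoblast nuclei and of Gcm1 transcripts per nucleus in sections of other zona-intact and zona-free placentas would decide between fewer cells and changed cells.

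Of the 10 splits of the 6 libraries into 3 against 3, which are too few for a share under 0.05 in any count, only the real one gave as many as 68 genes, the highest other count being 4, and by reads 415 against 4. For the looser limit the real split gave 844 and the highest other 337, so 1 of 10 splits was as large in both cases. For the gene lists 5 of 10 splits gave at least 12 calls, and the highest other gave 17.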
